A study of Homo sapiens with 4 samples.

How the data were processed

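Total RNA from MDA-MB-361 cells was measured on 4 single-colour Cy3 Agilent arrays, 1 for each of the groups DMSO, KW-2450, lapatinib and KW-2450 with lapatinib, all after 48 h. The groups were taken from the labels. Per the labels' protocols, RNA was extracted with TRIzol and labelled with the Quick Amp kit. Per the file headers, the arrays were extracted with Agilent Feature Extraction 10.7.3.1, which gave the deposited intensity of each spot, already background-subtracted and spatially detrended but not scaled between arrays. The median spot and background intensity columns deposited beside it were used only for an alternative. The authors also deposited a table of values with no stated scale. Set against the scanner values, its columns were log2 ratios to the DMSO array, with the DMSO column at 0 for every probe and medians of -0.027, -0.032 and -0.019 for KW-2450, lapatinib and the combination. The authors' log2 ratios followed the scanner ratios with correlations of 1.00 and differed by constants of 0.13, -0.038 and 0.18, and how those constants were chosen is not given in the sources used here.

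The spots of 41000 probes were used, after leaving out control spots and the 53 to 72 spots per array that the scanner software marked as outliers. The processed signal was put on the log2 scale and each array's 75th percentile subtracted. A probe entered a comparison if it was well above background on each array compared. Spots of a probe were averaged, then the probes of a gene. Gene names in the files are old, so probes were named through their RefSeq accessions with a gene table of GRCh38.p14, used for names only. Of the 41000 probes, 23680 (57.8%) matched 16422 genes, 5682 of them with more than 1 probe, and 17320 probes had no name. The 95% half-widths of a ratio came from 264 probes printed 10 times on each array, which cover spot error only, and from the spread over genes of the combination minus KW-2450 minus lapatinib plus DMSO. The number of arrays limits the precision.

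Each pair of arrays was compared by the log2 ratio per gene, counting genes at least 2-fold apart, and no p-value was computed from pairs of arrays. The excess over the sum is the combination minus KW-2450 minus lapatinib plus DMSO on the log2 scale. A gene well above background on 1 of the arrays compared was given a bound, the bright array's value against the higher of the dim array's own value and the lowest signal well above background there, written as at least N-fold. The bound is the mean over the gene's probes that were well above background on the bright array, and probes of the gene above background on neither array do not enter it. An additive limma fit with a term for each drug was run on the log2 values with 1 residual degree of freedom and Benjamini-Hochberg adjustment, as a secondary result. Shared use of the DMSO array was addressed by 100 simulated draws with no effect.

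Before the data were examined, 40 gene lists with 984 distinct symbols were fixed, 955 of them on the array, including leukocyte, endothelial and fibroblast markers. For each list the median log2 ratio, interquartile range and members at least 2-fold apart were counted. The percentile of the median was taken among 10000 random lists of the same size, matched on signal in 20 bins, as a description of these arrays. Lists with under 5 measured genes were given no percentile, which left 38. Named genes followed a rule also fixed before: the 10 highest and 10 lowest ratios over DMSO and the 5 highest and 5 lowest in other comparisons, among genes with a standard symbol whose brighter array lay above the median of probes well above background, the 3 largest bounds per direction, up to 4 members of each described list with the largest ratios, and the target and adaptor genes IGF1R, INSR, EGFR, ERBB2, ERBB3, ERBB4, IRS1 and IRS2. Of the bounds, 1 from a family of near-identical copies is not named, and some other genes that the rule takes are not reported here.

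Alternatives fixed before were median scaling, quantile normalization, cyclic loess, normexp background correction with an offset of 50, no filter on dim probes, only bright probes, the brightest probe per gene, outlier spots kept, the table of the authors' values, unmatched random lists and a signal-dependent prior variance in the limma fit. Chosen after the data were seen were scaling on 7 bright spike-in probes, all probes as units, and, within normexp, the median in place of the mean spot intensity with outlying local backgrounds replaced by the array's median. The position of each array on its slide was read from the file names. By those names the DMSO, KW-2450 and lapatinib arrays shared a slide, and the DMSO and combination arrays both lay at the first position of their slides. Slide could not be fitted as a block because the combination array was alone on its slide.

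The procedures were tested on simulated data over 11950 genes. For KW-2450 over DMSO the 2-fold rule found 2% of genes changed 1.5-fold, 52% of those changed 2-fold, 100% of those changed 3-fold and 2 of 11750 unchanged genes. For lapatinib over DMSO it found 2%, 42% and 96%, and 2 unchanged genes. The additive fit found 98% of 2-fold changes for KW-2450 and 96% for lapatinib, and 22% and 12% of 1.5-fold changes. The simulated effects were additive, with normal error of a fixed size per signal band and no slide effect or interaction. These rates may therefore not hold for the real arrays. Of 200 random lists, 3.5% fell outside the central 95%. Software was R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.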

Results

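Gene expression was measured in MDA-MB-361, an established estrogen receptor-positive breast cancer cell line with an amplified ERBB2 gene, after 48 h of treatment. Cells received the vehicle DMSO, KW-2450 alone, lapatinib alone, or the drugs together, with each drug at 100 nM. KW-2450 inhibits the tyrosine kinases of the IGF-1 receptor and the insulin receptor, and lapatinib inhibits those of EGFR and HER2, the product of ERBB2. Each of the 4 groups was measured on 1 single-colour array, so no difference has a replicate check and no p-value across genes is given for any pair of arrays. The 75th percentile of the processed signal was 1039 on the DMSO array, 917 with KW-2450, 1046 with lapatinib and 868 with both drugs. Between 67.5% and 68.6% of the 43376 spots were well above background on each array, and 0 were saturated.

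A log2 ratio between arrays had a 95% half-width from spot error of 0.49 for dim, 0.20 for middle and 0.17 for bright signals, in 3 bands of equal numbers of probes above background. The departure of the 4 arrays from additivity, which holds array error and any true interaction, gave wider half-widths of 0.57, 0.37 and 0.30. Differences of at least 2-fold lay outside both ranges. Ratios are relative to each array's 75th percentile, and scaling on the spike-in control spots in its place moved the median of all genes by 0.22 for lapatinib over DMSO, -0.24 for the combination over DMSO, -0.24 for the combination over KW-2450, -0.47 for the combination over lapatinib and -0.23 for KW-2450 over lapatinib. Single genes outside the groups are ranked among the brighter genes only, those whose brighter array lay above the median of probes well above background. The DMSO, KW-2450 and lapatinib arrays shared a slide and the combination array lay alone on another, so slide and combined treatment cannot be told apart. Gene groups were fixed before the data were examined, and a group is described as apart where its median lay outside the central 95% of 10000 random lists of the same size and signal.

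KW-2450 over DMSO addressed treatment with KW-2450 alone. Inhibition of the receptors by either drug was not measured on these arrays. FOXO target genes, which forkhead factors activate when AKT signalling is low, were higher as a group, with a median log2 ratio of 0.39 (interquartile range 0.21 to 0.58) over 34 measured genes. At least 2-fold higher were 4 of them, namely IRS2 (1.31), an adaptor of the insulin receptor, PIK3IP1 (1.08), an inhibitor of PI3K, FBXO32 (1.03), a ubiquitin ligase component, and TNFSF10 (1.01), the death ligand TRAIL. Proliferation and lipid synthesis genes were slightly lower, with medians of -0.34 over 48 DNA replication genes, -0.32 over 57 mitosis genes, -0.32 over 25 sterol synthesis genes and -0.30 over 21 fatty acid synthesis genes, and 0 members of these groups were 2-fold apart. Among the brighter genes, the largest ratio was that of TIMP3 (2.47), a secreted inhibitor of metalloproteinases, followed by PIP (1.62), a secretory protein of luminal breast cells.

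Of 12221 genes measured on the KW-2450 and DMSO arrays, 46 were at least 2-fold higher and 22 at least 2-fold lower, a split of 67.6% higher. Quantile normalization gave 36 higher and 29 lower (55.4% higher), and cyclic loess gave 37 and 29 (56.1% higher). With normexp background correction the counts were 12 and 2. The 8 called genes with several probes had every probe on the same side and at least 1.5-fold apart. Genes are called on the mean of these probes, which share each array. Agreement of probes, here and below, therefore does not check for an error of a dish or an array. Other brighter genes with high ratios were CHGB (1.31), a protein of secretory granules, FAXDC2 (1.29), the kinase SGK3 (1.10), LOXL4 (1.06), CREBRF (1.02) and KLHL24 (0.99). The lowest of the brighter genes were DRICH1 (-1.26), the transcription factor NEUROG1 (-1.16), RAB34 (-1.05), the condensin subunit SMC2 (-1.02), TUBB2B (-0.88), KISS1R (-0.88), the neuropeptide GAL (-0.83), the sterol sensor INSIG1 (-0.82), NEUROG3 (-0.81) and SPSB4 (-0.80). NEUROG1, KISS1R and NEUROG3 were also lower with lapatinib (-1.30, -1.17 and -1.36) and nearer DMSO with both drugs (-0.62, -0.28 and -0.44). For that pattern, position on the slide is weighed below.

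Among smaller group differences with KW-2450, glycolysis genes had a median of -0.26 over 22 genes, with SLC16A3 (-0.71) and ENO2 (-0.68) at the low end and PFKFB3 (0.83) on the other side. NRF2 target genes had a median of -0.18 over 22 genes, where AKR1C3 (-0.50) and AKR1C1 (-0.48) were among the lowest. Estrogen receptor targets had a median of 0.14 over 33 genes, with PDZK1 (0.69) and CELSR2 (0.55) among the highest. TGF-beta targets lay at 0.20 over 13 genes and immediate early genes at 0.16 over 17, the latter led by EGR2 (0.84) and FOS (0.74). MAPK output genes, which report the activity of the RAS to ERK cascade, were not apart from random lists, with a median of 0.020 over 23 genes. In all, 15 of 38 groups lay outside the central 95%, against 1.9 expected for independent lists whose members do not move together. Genes of a group can move together between any pair of dishes, so this count does not by itself show a drug effect. For genes near background on an array a bound was taken from the probes above background on the other. Lower with KW-2450 were 1 of the 2 probes of FXYD2, at least 14.7-fold, 1 of the 2 of SPART, at least 9.29-fold, and 1 of the 3 of KCNE5, at least 7.62-fold, and their other probes were above background on neither array. In the other direction, with 1 probe each, LGI4 was at least 6.23-fold higher, TACR1 at least 5.91-fold and RHCG at least 5.74-fold.

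Lapatinib over DMSO addressed treatment with lapatinib alone. MAPK output genes were the group farthest below DMSO, with a median of -0.96 (interquartile range -2.04 to -0.33) over 20 genes, of which 9 were at least 2-fold lower and 0 higher. The lowest members were ETV4 (-3.04), an ETS factor induced by ERK, DUSP6 (-2.78), an ERK phosphatase, EGR3 (-2.56) and SPRY4 (-2.41), a feedback inhibitor of receptor signalling. FOXO targets were higher, at 0.35 over 34 genes with PIK3IP1 (0.84), IRS2 (0.77) and CCNG2 (0.75) in front and 0 at least 2-fold apart. Estrogen receptor targets had a median of 0.32 over 33 genes, with 4 at least 2-fold higher, among them SGK3 (1.23), CXCL12 (1.17) and PGR (1.13), and FHL2 (-1.29) lower.

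Of 12133 genes measured on the lapatinib and DMSO arrays, 55 were at least 2-fold higher and 128 lower, a split of 30.1% higher. Scaling on the spike-in spots turned the split to 131 higher and 81 lower (61.8% higher), and normexp correction gave 9 and 68. All 32 called genes with several probes had their probes on the same side and at least 1.5-fold apart. The highest ratios of the brighter genes belonged to SOCS2 (2.37), a suppressor of cytokine signalling, PLEKHS1 (1.61), ADHFE1 (1.36), the proton pump subunit ATP6V1B1 (1.33), SGK3 (1.23), IQCN (1.19), CITED4 (1.10), the carbonic anhydrase CA2 (1.08), LOXL4 (1.08) and SERPINF1 (1.05). Beside DUSP6 and SPRY4, the lowest of the brighter genes were PECAM1 (-3.17), an adhesion molecule, DOK7 (-2.25), GDF15 (-2.21), a stress-responsive cytokine, the antimicrobial peptide CAMP (-2.19), DUSP13A (-2.14), SLC25A18 (-2.10), PLEKHA4 (-2.04) and the immediate early factor EGR1 (-2.03). DUSP13A shares its locus with a neighbouring phosphatase gene, so its probe may not be specific.

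Fatty acid synthesis genes had a median of -0.38 over 22 genes with lapatinib, with SCD (-1.34), the stearoyl-CoA desaturase, lowest. Sterol synthesis genes lay at -0.34 over 25 genes, with STARD4 (-1.44) and INSIG1 (-0.99) lowest. Immediate early genes lay at -0.35 over 16 genes, glycolysis genes at -0.25 over 22 (-0.024 with spike-in scaling) and NRF2 targets at -0.23 over 22 (-0.0031 with spike-in scaling), with AKR1B10 (-1.99) and AKR1C1 (-1.27) lowest in the last. Mitosis genes had a median of -0.20 over 57 genes, which turned to 0.020 with spike-in scaling, and DNA replication genes one of 0.055 over 48. Spike-in scaling also gave -0.15 for fatty acid synthesis, -0.11 for sterol synthesis, -0.12 for immediate early and 0.28 for DNA replication genes. Leukocyte markers were also apart, at -0.61 over the 5 measured of 14 listed genes, with TYROBP (-0.70), FCER1G (-0.64) and CD68 (-0.61) lowest. In all, 16 of 38 groups lay outside the central 95%. Near background with lapatinib and not with DMSO was the ETS factor ETV5, at least 7.90-fold lower on both probes. Lower on 1 probe, with the others above background on neither array, were FXYD2 (at least 14.6-fold, 1 of 2 probes) and KCNE5 (at least 7.55-fold, 1 of 3), and higher in the same way was FGFBP2 (at least 11.1-fold, 1 of 2). The FXYD2 and KCNE5 bounds used the same DMSO values as those with KW-2450, so an error on the DMSO array would enter both comparisons. SLC17A1, with 1 probe, was at least 9.34-fold higher.

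KW-2450 over lapatinib compared the drugs directly on 1 slide. MAPK output genes were higher with KW-2450 by a median of 0.97 (interquartile range 0.36 to 2.21) over 20 genes, 10 of them at least 2-fold, led by ETV4 (3.32), SPRY4 (2.65), EGR3 (2.60) and DUSP6 (2.59). PECAM1 (3.34), CHGB (2.58) and EGR1 (2.52) were also high among the brighter genes. DNA replication genes lay lower with KW-2450, at -0.37 over 48 genes, all 48 below 0, and mitosis genes at -0.094 over 57. SOCS2 (-1.68), PLEKHS1 (-1.59), the hormone precursor TRH (-1.23), RAMP1 (-1.22) and EVL (-1.08) were the lowest of the brighter genes, and the 2 probes of EVL differed, at -1.86 and -0.31. Estrogen receptor targets had a median of -0.10 over 34 genes, with PGR (-1.10) and CXCL12 (-1.07) lowest and FHL2 (1.05) highest.

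Of 12171 genes measured on the KW-2450 and lapatinib arrays, 126 were at least 2-fold higher with KW-2450 and 37 lower, a split of 77.3% higher. Spike-in scaling gave 69 and 86 (44.5% higher), and normexp correction gave 63 and 4. Milk and secretory genes lay at 0.23 over 12 genes (0.0037 with spike-in scaling), with S100A8 (2.55) and PIP (1.80) highest. Immediate early genes lay at 0.45 over 16 genes. Basal and mesenchymal markers had a median of 0.20 over 16 genes and HER receptors and ligands of 0.20 over 11, both turning below 0 with spike-in scaling (-0.026 and -0.021). Leukocyte markers lay at 0.51 over 5 genes.

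The ratios of KW-2450 and lapatinib over DMSO correlated across 11950 genes with Pearson's r = 0.514 and Spearman's rho = 0.582, where genes are not independent replicates. Both ratios share the DMSO array, and arrays simulated with no effect gave r = 0.50 with either spot or array error. The covariance was 0.0411, against 0.00916 and 0.0218 in those simulations. The simulated array error was drawn from a robust spread, 0.136 over all genes, which leaves out the tails. The ordinary standard deviation of the same contrast was 0.203. The larger covariance therefore does not show a shared effect of the drugs. With 1 DMSO array the control could not be split, so part of the excess may come from it. At least 2-fold higher with each drug were 7 genes, where independent lists of 41 and 55 genes would share 0.189, and at least 2-fold lower with each were 9, where lists of 18 and 113 would share 0.170.

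The combination over DMSO addressed treatment with both drugs together. Mitosis genes were lower in every case, with a median of -2.41 (5.30-fold, interquartile range -2.56 to -2.12) and 57 of 57 measured genes at least 2-fold lower, led by the centromere protector SGO1 (-3.33), the kinesin KIF14 (-3.13), KIF2C (-2.83) and the mitotic kinase AURKB (-2.81). DNA replication genes had a median of -1.38 over 48 genes, 37 of them at least 2-fold lower, with RRM2 (-2.31), a ribonucleotide reductase subunit, MCM10 (-2.29) and DSCC1 (-2.20) lowest. FOXO targets had a median of 1.07 (2.11-fold, interquartile range 0.53 to 1.4) over 34 genes, with 19 at least 2-fold higher and 1 lower, led by IRS2 (2.41), TNFSF10 (2.39), PIK3IP1 (2.28) and FBXO32 (2.06). Sterol synthesis genes lay at -0.98 over 24 genes with 12 at least 2-fold lower, including INSIG1 (-3.03) and ACAT2 (-1.95). Fatty acid synthesis genes lay at -0.76 over 21 genes with 8 at least 2-fold lower, including SCD (-3.22) and the desaturases FADS2 (-2.80) and FADS1 (-1.98).

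**Figure D1:**
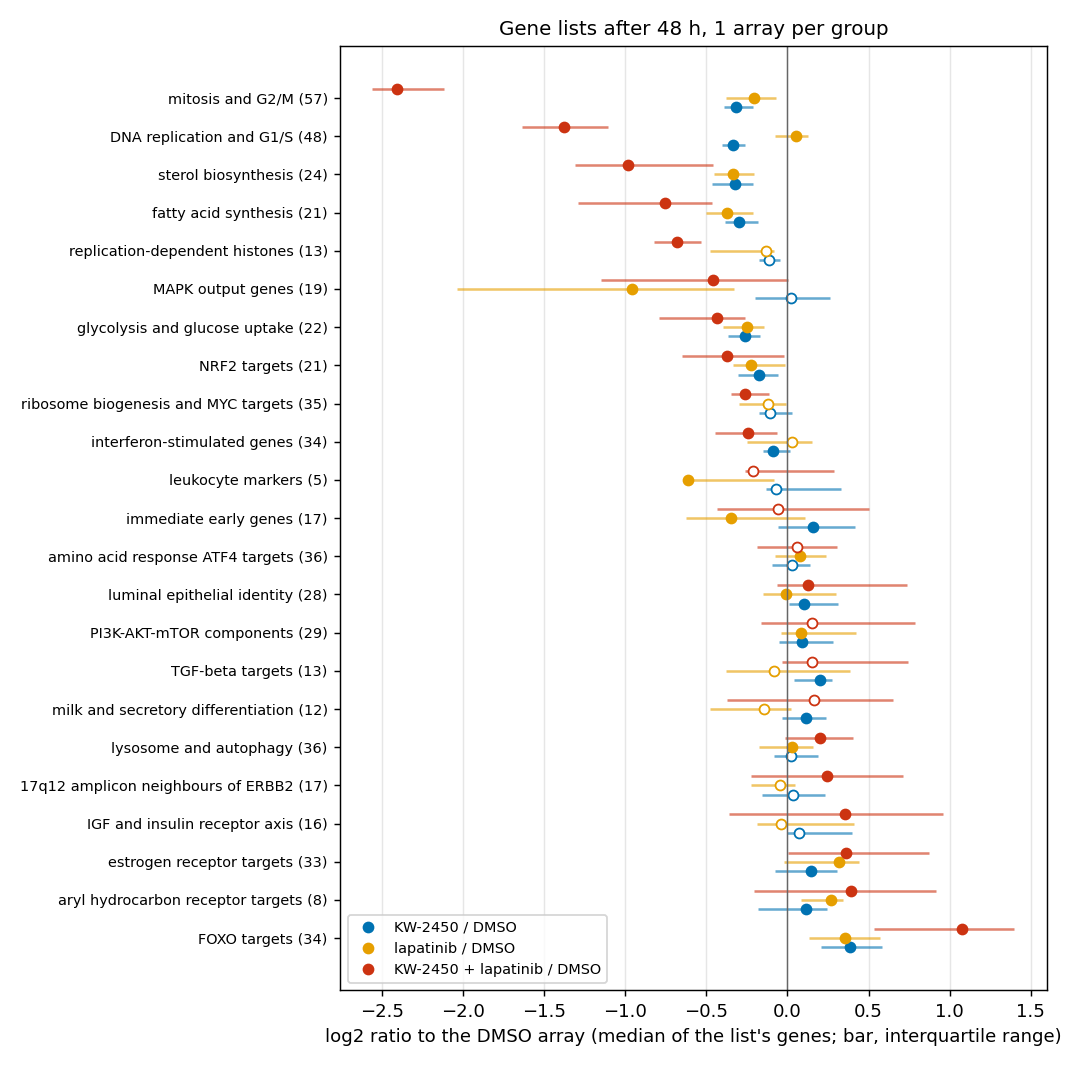
Median log2 ratio to the DMSO array of each gene group (points) with the interquartile range of its members (bars), for KW-2450, lapatinib and both drugs, 1 array each; the number in brackets is the number of genes measured with both drugs, and open points are medians inside the central 95% of random lists. With both drugs the mitosis group lies at -2.41 and the FOXO group at 1.07, against -0.32 and 0.39 with KW-2450 and -0.20 and 0.35 with lapatinib; the lapatinib value of the mitosis group turned to 0.020 with spike-in scaling.

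Of 12070 genes measured on the combination and DMSO arrays, 422 were at least 2-fold higher and 605 lower, a split of 41.1% higher. Spike-in scaling gave 224 higher and 976 lower (18.7% higher), and normexp correction gave 209 higher. Among 217 called genes with several probes, 215 had every probe on the same side and 206 had every probe at least 1.5-fold apart. The highest ratios of the brighter genes were those of TIMP3 (3.61), SOCS2 (3.48), DEPP1 (3.39), a FOXO-regulated gene, CALCOCO1 (3.02), an autophagy receptor, WNK4 (2.65), CYP1A1 (2.59), the classical aryl hydrocarbon receptor target, IQCN (2.56), TDRD10 (2.49), SGK3 (2.46) and IRS2 (2.41). Beside SCD, INSIG1, FADS2, KIF2C and AURKB, the lowest of the brighter genes were ARHGAP11A (-2.90), SHCBP1 (-2.78), FAM72D (-2.77), PTTG2 (-2.76) and KIF4A (-2.74). FAM72D and PTTG2 have near-identical relatives, so their probes may report those as well. For TDRD10, FADS2 and ARHGAP11A, probes not well above background on both arrays were left out, so each ratio rests on 1 probe. Not well above background with both drugs were AKR1B10, at least 19.8-fold lower than with DMSO, and its relative AKR1B1, at least 12.7-fold lower. The same held for 1 of the 2 probes of SPART, at least 9.45-fold lower, with its other probe above background on neither array. The SPART bound used the same DMSO value as that with KW-2450. In the other direction MED18 was at least 8.77-fold higher, the secreted lipocalin PAEP at least 7.99-fold and PELI2 at least 7.16-fold.

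MAPK output genes had a median of -0.46 over 19 genes with both drugs, with 5 at least 2-fold lower, EGR3 (-2.03), PHLDA1 (-1.69), KCNN4 (-1.61) and DUSP6 (-1.53) in front, and 1 at least 2-fold higher. Glycolysis genes lay at -0.43 over 22 genes, with SLC16A3 (-1.21) and the lactate dehydrogenase subunits LDHA (-1.06) and LDHB (-1.03) lowest. Replication-dependent histones lay at -0.68 over 13 genes with H1-5 (-1.88) lowest, and ribosome biogenesis genes at -0.26 over 35, in which ODC1 (-1.39) and MYC (1.37) stood at opposite ends. Estrogen receptor targets had a median of 0.36 over 33 genes (0.12 with spike-in scaling). At least 2-fold higher were 7 of them, including STC2 (1.53) and IGFBP4 (1.49). In all, 17 of 38 groups lay outside the central 95%. Endothelial and fibroblast markers had 3 measured genes each and were given no percentile, and leukocyte markers were not apart, at -0.21 over 5 genes.

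**Figure D2:**
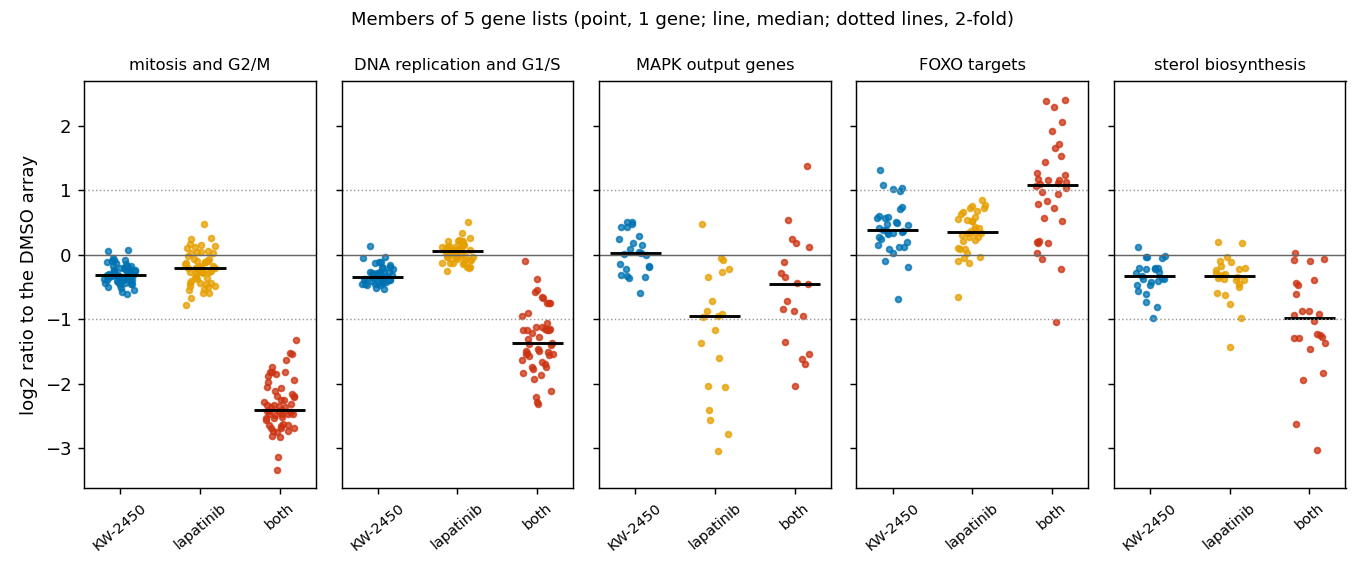
Log2 ratio to the DMSO array of each measured gene (point) in 5 gene groups, for KW-2450, lapatinib and both drugs, 1 array each; black lines are medians and dotted lines mark 2-fold. All 57 mitosis genes lie below the lower 2-fold line with both drugs and 0 do so with either drug alone.

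The genes of the drug targets and their adaptors were read on all 4 arrays. INSR, the insulin receptor, had log2 ratios over DMSO of 0.73 with KW-2450, 0.62 with lapatinib and 1.17 with both, and IGF1R had 0.49, 0.32 and 1.09. IRS2 had 1.31, 0.77 and 2.41, whereas IRS1 had 0.16, -0.18 and 0.34, with the lapatinib value turning to 0.038 under spike-in scaling. ERBB3 had 0.41, 0.21 and 1.04, ERBB4 had 0.08, 0.76 and 1.07, and EGFR had 0.019, 0.43 and 0.61, its KW-2450 value turning to -0.055 with quantile normalization. The ERBB4 values leave out a probe that was not well above background. ERBB2 had 0.23, -0.21 and 0.25, and its lapatinib value turned to 0.012 with spike-in scaling. That scaling moves every value with both drugs by -0.24, which is close to the whole 0.25 of ERBB2. The whole IGF and insulin receptor group lay at 0.36 over 16 genes with both drugs, with 4 at least 2-fold higher and GRB14 (-1.24) among those lower.

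The combination over KW-2450 addressed what lapatinib did in the presence of KW-2450. Mitosis genes had a median of -2.08 with 57 of 57 at least 2-fold lower, and DNA replication genes of -0.98 with 23 of 48. FOXO targets had a median of 0.63 over 34 genes with 5 at least 2-fold higher, including TNFSF10 (1.37) and MXI1 (1.15). Spike-in scaling lowered the FOXO median to 0.39. MAPK output genes lay at -0.75 over 19 genes with 5 at least 2-fold lower, including EGR3 (-2.07) and PHLDA1 (-1.55). Sterol synthesis genes lay at -0.65 and fatty acid synthesis genes at -0.44, over 24 and 21 genes.

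Of 12172 genes, 165 were at least 2-fold higher with both drugs than with KW-2450 and 396 lower, a split of 29.4% higher. Spike-in scaling gave 66 and 608 (9.79% higher), and normexp correction gave 46 and 255. Among the brighter genes, SOCS2 (2.79), CYP1A1 (2.06), WNK4 (1.82), CACNG1 (1.80) and IQCN (1.78) were highest, and CLCA2 (-2.67), SCD (-2.64), the spindle checkpoint kinase BUB1 (-2.48), the growth factor BMP7 (-2.46) and KIF2C (-2.44) lowest. The BMP7 ratio leaves out a probe that was not well above background on both arrays. In p53 target genes the median was -0.19 over 27 genes, with GDF15 (-1.90) and CDKN1A (-1.39), which encodes the cell cycle inhibitor p21, lowest. Basal and mesenchymal markers lay at -0.25 over 14 genes, with TP63 (-1.33) and FN1 (-1.08) lowest, and housekeeping genes at -0.20 over 20, with TUBB (-1.17) lowest. In all, 20 of 38 groups lay outside the central 95%.

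The combination over lapatinib addressed what KW-2450 did in the presence of lapatinib. Mitosis genes had a median of -2.13 with 56 of 57 at least 2-fold lower, and DNA replication genes of -1.42 with 36 of 48. FOXO targets had a median of 0.64 over 34 genes with 8 at least 2-fold higher, TNFSF10 (1.83), IRS2 (1.63), PIK3IP1 (1.44) and FBXO32 (1.38) in front. Spike-in scaling lowered the FOXO median to 0.18. MAPK output genes were higher with both drugs than with lapatinib, by a median of 0.44 over 19 genes with 5 at least 2-fold higher, including ETV4 (2.69), MAFF (2.15) and SPRY4 (1.53), although spike-in scaling turned the median to -0.026. Sterol synthesis genes lay at -0.67 over 24 genes and fatty acid synthesis genes at -0.41 over 20.

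Of 12079 genes, 230 were at least 2-fold higher with both drugs than with lapatinib and 414 lower, a split of 35.7% higher. Spike-in scaling gave 59 and 1034 (5.40% higher), and normexp correction gave 91 and 263. Among the brighter genes, DEPP1 (3.12), TIMP3 (2.76), TDRD10 (2.58), PIP (2.56) and FAXDC2 (2.29) were highest, and SHCBP1 (-2.60), the kinetochore genes SPC25 (-2.55) and NDC80 (-2.54), the mitotic kinase CDK1 (-2.55) and topoisomerase TOP2A (-2.53) lowest. The TDRD10 ratio leaves out a probe that was not well above background on both arrays. CDK inhibitors and cyclins D and G lay at -0.40 over 15 genes, with CDKN2C (-1.75) and CDKN2D (-1.37) lowest. Heat shock genes lay at -0.17 over 21, with HSPA4L (-1.39) lowest. In all, 21 of 38 groups lay outside the central 95%.

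The 2 x 2 layout allowed the combination to be set against the sum of the single-drug log2 ratios. Mitosis genes lay below that sum by a median of -1.82 (interquartile range -2.04 to -1.63) with 56 of 57 at least 1 below it, and DNA replication genes by -1.10 with 26 of 48. The brighter genes farthest below were TOP2A (-2.44), the centromere chaperone HJURP (-2.31), SHCBP1 (-2.24), NDC80 (-2.23) and DEPDC1B (-2.22). MAPK output genes lay above the sum by 0.42 over 19 genes, led by ETV4 (2.41) and MAFF (1.64), and FOXO targets by 0.23 over 34, and spike-in scaling turned these medians to -0.049 and -0.23. Sterol synthesis genes lay at -0.29 over 24 genes, with INSIG1 (-1.23) among the lowest.

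Of 11950 genes well above background on all 4 arrays, 96 lay at least 1 above the sum and 297 at least 1 below, which spike-in scaling moved to 26 and 830 and normexp correction to 30 and 177. The brighter genes farthest above were PTH2 (1.99), the fatty acid receptor FFAR4 (1.93), FOXB1 (1.88), NEUROG1 (1.83) and KISS1R (1.77). On the combination array, 76 genes were at least 2-fold higher and 279 at least 2-fold lower than on each of the 3 other arrays. Slide and any error of the combination array enter these values in full.

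**Figure D3:**
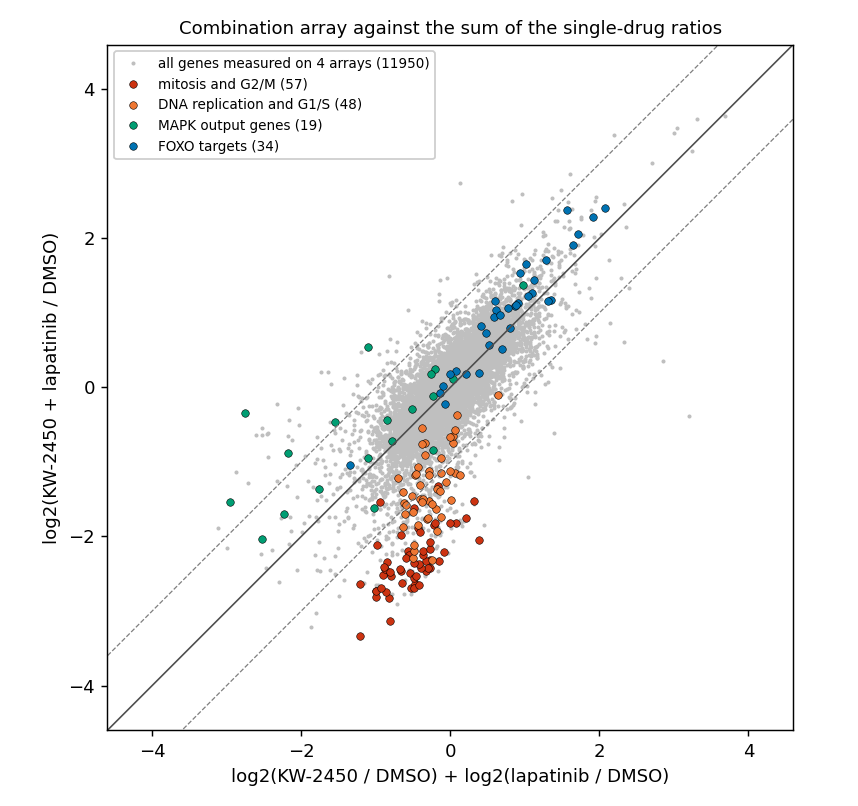
Log2 ratio to DMSO on the combination array (vertical axis) against the sum of the log2 ratios of KW-2450 and lapatinib to DMSO (horizontal axis), for 11950 genes (grey) and 4 gene groups (colours); the solid line is equality and the dashed lines mark a departure of 1. Mitosis genes (median -1.82) and DNA replication genes (median -1.10) lie below the line; the FOXO median of 0.23 and the MAPK output median of 0.42 turned below 0 with spike-in scaling.

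The KW-2450 effect without lapatinib and the effect with it share no array, and they correlated across genes with Pearson's r = 0.565 (bootstrap range over genes 0.546 to 0.583) and Spearman's rho = 0.576, with the same sign in 70.5% of 11950 genes. The lapatinib effect without and with KW-2450 gave r = 0.509 (0.491 to 0.529), rho = 0.519 and the same sign in 68.9%. Genes at least 2-fold higher with KW-2450 and with both drugs numbered 27, against 1.41 for independent lists, and 9 were lower in each, against 0.902. For lapatinib the shared numbers were 40 higher, against 1.89, and 69 lower, against 5.66. These overlaps share the DMSO array, and part of the excess may come from it.

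An additive limma fit over the 4 arrays, with 1 residual degree of freedom that holds interaction, slide and array error, found 0 genes for KW-2450 at a Benjamini-Hochberg adjusted p of 0.05, with 2032 at an unadjusted p under 0.05. The smallest adjusted p was 0.192. For lapatinib it found 0 genes, with 2315 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0631. Among the genes at that smallest value were SOCS2, with an average lapatinib log2 ratio of 2.58, and CAMP, with -2.09. With a prior variance that follows the signal, the fit found 1 gene for KW-2450 and 100 for lapatinib. Some other alternatives also moved these counts from 0, as listed in the part on processing.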

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

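The tests of both patterns weighed in this part were chosen after their results were seen. DNA replication genes were picked out because the lapatinib effect lay on opposite sides of the random lists with and without KW-2450. Over DMSO, lapatinib gave a median log2 ratio of 0.055 over 48 genes, with UNG (0.51) and CCNE2 (0.34) highest. That median was close to 0, with 28 genes above 0, 20 below and 0 at least 2-fold apart. It stood apart only from random lists, whose median was -0.069. In the presence of KW-2450 the median was -0.98, with all 48 genes below 0 and RRM2 (-1.98), MCM10 (-1.93) and DSCC1 (-1.75) lowest. The difference between the effects is the excess over the sum, with a median of -1.10, 48 of 48 genes below 0 and no random list of 10000 as low. It was not tested against replicates, since each group has 1 array.

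Probes without a gene name, which no comparison of genes uses, were picked out because they leaned the other way from named ones. Between the combination and DMSO arrays, 551 of 9435 were at least 2-fold higher and 257 lower, against 599 and 807 of 17224 probes with a name. The share of higher calls was 70.7%, 66.0% and 61.7% for dim, middle and bright signals without a name and 48.8%, 43.4% and 31.6% with one.

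Mitosis and DNA replication genes lay far below the sum of the single-drug log2 ratios on the combination array. A trend with signal is argued against as the whole cause, since the mitosis genes kept a median excess of -1.87 after cyclic loess. Scaling moves all genes alike, so only the gap between mitosis and housekeeping genes argues against it as the whole cause. Their median excesses were -1.82 and -0.14, and with spike-in scaling -2.29 and -0.60. The housekeeping value alone depends on the scaling. Position on the slide cancels between the DMSO and combination arrays, where the mitosis median was -2.41. The slide, or the dish of cells behind the combination array, cannot be told apart from the treatment, because 0 arrays of another group lay on the second slide. An effect of the drugs together on proliferation was not tested, since no repeat of the combination on another slide and no cell cycle measurement was at hand.

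MAPK output genes were low with lapatinib and less low with both drugs. An error of the DMSO or lapatinib array is argued against as the whole cause of the low values, because the combination over KW-2450, which uses neither array, gave a median of -0.75, below all 10000 random lists. The smaller difference with both drugs rests on an excess of 0.42, and an error of 1 array cannot be told apart from an effect of the treatment with 1 array per group. Spike-in scaling took that excess to -0.049, so its direction depends on the scaling. A weaker response of these genes to lapatinib beside KW-2450 may therefore be real or may come from an array or its scaling.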

How the results depend on the processing

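Spike-in scaling and all probes as units were chosen after the data were seen, as were the substitutions within normexp. No paired analysis was possible because each group has 1 array. The direction of the 98 named ratios of at least 2-fold was kept in every alternative that measured them, and 85 to 98 of them stayed at least 2-fold where all were measured, with 70 of 71 among bright probes only. Median scaling, spike-in scaling and the authors' values move each comparison by a constant below 2-fold, so the direction could not change there. Of 120 group medians outside the central 95% of random lists, between 103 and 118 stayed outside on the same side in each alternative. This range leaves out median scaling, spike-in scaling and the authors' value table. Those move a group and its random lists by the same constant, so they say nothing about the percentiles. Median scaling, quantile normalization, cyclic loess, the brightest probe per gene, kept outlier spots and the authors' value table left every count of genes at least 2-fold apart within 1.5 times. Normexp compresses dim signals through its offset, the filters change which probes enter and unnamed probes add units, and for other moves the cause was not tested. Spot error gave a 95% half-width of 0.49 for dim and 0.17 for bright signals. Slide as a block could not be run.

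In the following lists, counts are of genes at least 2-fold higher and then lower. With normexp they were 12 and 2 for KW-2450 over DMSO, 9 and 68 for lapatinib over DMSO, 209 higher for the combination over DMSO, 46 and 255 for the combination over KW-2450, 91 and 263 for the combination over lapatinib and 63 and 4 for KW-2450 over lapatinib. The combination exceeded each other array in 29 genes, and 30 genes lay at least 1 above the sum and 177 below. Correlations of the effect without and with the other drug were 0.611 for KW-2450 and 0.541 for lapatinib.

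With no filter on dim probes the counts, in the same order, were 376 and 279, 259 and 519, 839 and 1052, 448 and 817, 646 and 690, and 557 and 194. The combination exceeded each other array in 257 genes, 660 lay above the sum and 779 below, and the correlations were 0.258 and 0.268. With only bright probes the counts were 12 and 4, 12 and 50, 172 and 343, 53 and 217, 66 and 217, and 45 and 5. The combination lay beyond each other array in 27 genes higher and 166 lower, 19 lay above the sum and 153 below, and the correlations were 0.627 and 0.571, with 0.572 between the drugs.

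With spike-in scaling the counts were 131 and 81 for lapatinib over DMSO, 224 and 976 for the combination over DMSO, 66 and 608 over KW-2450, 59 and 1034 over lapatinib, and 69 and 86 for KW-2450 over lapatinib. The combination lay beyond each other array in 20 genes higher and 472 lower, and 26 lay above the sum and 830 below. With all probes as units the counts were 120 and 64, 130 and 260, 1150 and 1064, 426 and 685, 583 and 707, and 240 and 73. Beyond each other array lay 205 higher and 463 lower, 292 lay above the sum and 546 below, and the correlations were 0.501 and 0.466, with 0.553 between the drugs.

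The additive limma fit found 0 genes for each drug as reported. For KW-2450 it found 1 with bright probes, 1 with a signal-dependent prior and 366 with spike-in scaling. For lapatinib it found 13 with median scaling, 27 with normexp, 25 with bright probes, 6 with the authors' value table, 100 with a signal-dependent prior and 203 with spike-in scaling. In other alternatives it found 0. With spike-in scaling the prior degrees of freedom were infinite, so all genes shared a common error variance. The counts of 366 and 203 are therefore not comparable with the others.

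Some group medians changed sign. For lapatinib over DMSO, luminal genes moved from -0.011 to 0.098 with quantile normalization, 0.093 with cyclic loess and 0.21 with spike-in scaling. Lysosome genes moved from 0.026 to -0.0067 with normexp and -0.0021 with the authors' values, and mitosis genes to 0.020 with spike-in scaling, which left glycolysis genes at -0.024 and NRF2 targets at -0.0031. Spike-in scaling also turned luminal and lysosome genes for the combination over DMSO (-0.11 and -0.042) and over KW-2450 (-0.16 and -0.075). For the combination over lapatinib it gave -0.036 for the amplicon neighbours of ERBB2, -0.21 for the IGF and insulin receptor axis, -0.026 for MAPK output, -0.18 for TGF-beta targets, -0.12 for aryl hydrocarbon receptor targets, -0.29 for estrogen receptor targets, -0.14 for immediate early, -0.33 for luminal and -0.27 for lysosome genes. For KW-2450 over lapatinib it gave -0.11 for the amplicon neighbours, -0.021 for HER receptors and ligands, -0.084 for the IGF axis, -0.026 for basal and mesenchymal markers, -0.087 for ribosomal proteins and -0.096 for unfolded protein response chaperones. For the excess over the sum it gave -0.22 for the amplicon neighbours, -0.23 for FOXO targets, -0.23 for the IGF axis, -0.049 for MAPK output, -0.29 for ribosomal proteins and -0.31 for lysosome genes. By construction spike-in scaling moves every gene of an array by 1 constant.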

Other observations

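The tests of the pattern in the last paragraph of this part were set before their results were seen, and S1PR3, the endothelial markers and the spike-in values were chosen after. Interferon-stimulated genes were lower with both drugs, with a median log2 ratio over DMSO of -0.24 over 34 genes, among them IFIT1 (-2.23), BST2 (-2.01) and OAS3 (-1.31), while STAT2 (1.01), a transcription factor of the same pathway, was higher. With KW-2450 alone the median was -0.091, and with lapatinib alone 0.027, inside the range of random lists. Aryl hydrocarbon receptor targets split with both drugs, where CYP1A1 (2.59) and TIPARP (1.08) were higher and LRP8 (-1.89) and UGT1A6 (-1.02) lower. Their median was 0.39 over 8 genes (0.15 with spike-in scaling). NRF2 targets also split, around a median of -0.37 over 21 genes, with AKR1C1 (-2.46) and AKR1C3 (-1.43) lower and HMOX1 (1.18), heme oxygenase, higher. The 21 leave out AKR1B10, a member not well above background with both drugs and at least 19.8-fold lower than with DMSO.

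Genes next to ERBB2 on its amplicon did not move as a block with both drugs. Over 17 genes the median was 0.25 (0.0031 with spike-in scaling), with NEUROD2 (1.44), THRA (1.43) and GSDMB (1.42) higher and PPP1R1B (-1.74) lower. Luminal identity genes had a median of 0.13 over 28 genes, which spike-in scaling turned to -0.11, with PIP (2.38), the epithelial factor ELF3 (1.71) and AGR3 (1.31) highest. Lysosome and autophagy genes lay at 0.20 over 36 genes, turned to -0.042 by spike-in scaling, with the cathepsin CTSF (1.85), ATG14 (1.16) and GABARAPL1 (1.11) highest. Cytosolic ribosomal proteins were inside the range of random lists with KW-2450, lapatinib and both drugs over DMSO. The receptor gene S1PR3 alone was at least 2-fold apart in opposite directions under KW-2450, lower without lapatinib and higher with it, among 11950 genes. Endothelial markers had 3 measured genes, PECAM1, VWF and ESAM, with log2 ratios over DMSO of -2.15, -1.34 and -0.53 with both drugs, and 3 measured fibroblast markers had a median of 0.036.

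The 7 bright spike-in probes did not follow the 75th percentile on every array. Relative to DMSO they lay 0.0028 above it with KW-2450, -0.22 with lapatinib and 0.24 with both drugs. These values are as large as many of the group medians, and no array repeats a group.

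The 96 genes at least 1 above the sum of the single-drug log2 ratios, such as PTH2 (1.99) and FOXB1 (1.88), include 11 that were at least 0.5 lower on both single-drug arrays and within 0.5 of DMSO on the combination array. Position on the slide is a candidate explanation, as the DMSO and combination arrays share a position that the single-drug arrays do not. Over the 96 genes as a set, the KW-2450 median argues against position as the whole cause, if position lowers both single-drug arrays alike. The median of the 96 over DMSO was -0.12 (bootstrap range -0.28 to 0.031) for KW-2450, -0.68 for lapatinib and 0.39 (0.16 to 0.65) for the combination. The 96 genes were picked by their excess, which favours low single-drug values and high combination values. The -0.68 and 0.39 therefore decide nothing, and position acting on the lapatinib array only stays open. On the combination array 29 genes were at least 1 higher than with DMSO. Spike-in scaling moves every value of the combination over DMSO by -0.24, so the 0.39 depends on the scaling. The set medians do not speak for single genes, and 26 of the 96 were at least 0.5 lower than DMSO on both single-drug arrays. For those 26, position stays open. A patch of neighbouring spots stays open, since the median distance of the 109 probes of the 96 genes to the nearest other lay at percentile 18.8 of 2000 random sets. No biological explanation of these genes was tested, including the combined treatment.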
